A study of Mus musculus with 29 samples.

How the data were processed

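Splenic B cells of IgE reporter mice (C57BL/6, 8 weeks) were cultured on a fibroblast feeder expressing CD40L and BAFF, per the labels' protocols, with no added cytokine, IL-4, IL-13, IL-21, or IL-21 and IL-13. CD19-positive, propidium iodide-negative cells were sorted as IgE reporter positive or IgG1 positive. Libraries were made from 10 ng of total RNA with a 3' mRNA kit, per the labels' protocols. The submitters' processing notes name STAR 2.7.0c, featureCounts 1.6.0 and the builds mm10 and GRCm38.p6, without the role of each, the annotation or the step to the deposited values. The number and sex of the mice, the time in culture and the cytokine doses are not stated, nor whether a replicate is a mouse, a culture or a sort. The labels are ambiguous about a pre-culture with IL-4 and whether all groups shared it.

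The deposited values were read as TPM made by the authors: each library summed to 994301.8 to 997132.3, values were rounded to 1 decimal, and low values multiplied by exon length fell on whole steps. Exon lengths from GENCODE M21 matched 24874 of the 25939 genes listed. The unit itself is not named in the files. Because 3' tags do not grow with transcript length, division by length scales each gene's level, so levels of different genes are not compared here on an absolute scale. A gene's ratio between libraries is unaffected. Length still affects which genes reach the 5 TPM needed for testing, and how far the added 1 TPM shrinks a fold change. Reads of near-identical genes can be split or lost in counting, so the values of Ighg1 beside the other gamma constant genes, Bcl2a1b and Ly6c2 are uncertain in level. Gene positions are from GENCODE M21 on GRCm38, 1-based. The depth per library was estimated here from the smallest step, since TPM keeps no read number.

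A count model had been planned before the data were examined, together with the groups, comparisons, gene lists and alternatives. The values proved to be TPM, so limma 3.58.1 in R 4.3.3 was used in its place on log2(scaled TPM + 1). Genes with at least 5 TPM in at least 2 libraries were tested (10626). Libraries were scaled by an unweighted trimmed mean of log ratios computed here, trimming 0.3 of the log ratios and 0.05 of the mean levels at each end, which gave factors of 0.791 to 1.28. The model held 10 group means over all 29 libraries, with a variance trend on the mean level (residual df 19, prior df 6.53). All groups shared 1 estimate of the spread because each held only 2 or 3 libraries. Fold changes are on the log2(scaled TPM + 1) scale and understate changes of genes near 1 TPM. Significance was a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 21 comparisons. These were IgE against IgG1 in each culture and as a mean over the 5 cultures, each cytokine against none in each isotype, IL-21 with IL-13 against IL-21 alone, IL-13 against IL-4, and the difference of the isotypes' responses. The p-values measure the spread between these samples, which may be technical replicates.

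Genes named in the text followed a rule: in each comparison the 10 largest positive and 10 largest negative log2 fold changes among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1 and a mean of at least 5 TPM (planned as CPM) in the higher group. No overlap between the libraries compared was allowed (for the mean over cultures, the same sign in all 5). Immunoglobulin variable, diversity and joining segments, predicted genes, pseudogenes and mitochondrial genes were left out. In addition 22 preset genes were examined whatever their values, of which 18 were tested. The text gives their calls and a part of the values that did not pass, and for each gene list described up to 4 members with the smallest p. From the ranked genes the text names those whose call held in every fit that left out 1 library, unless it says otherwise. These were 20 of 20 for the mean of IgE against IgG1 and for IL-13 against IL-4. They were 7 of 19 without added cytokine, 11 of 20 with IL-4, 12 of 20 with IL-13, 13 of 20 with IL-21 and 10 of 20 with IL-21 and IL-13 between isotypes. For the cytokines against none they were 18, 5, 15 and 17 of 20 in IgE cells (IL-4, IL-13, IL-21, both), and 8 of 20, 0 of 5, 9 of 20 and 7 of 20 in IgG1 cells. For IL-21 with IL-13 against IL-21 they were 5 of 17 in IgE and 0 of 5 in IgG1 cells. A gene below the level for testing in such a fit was counted as not held. Slpi, Prg2, Mzb1, Klhdc2, Nfkbia and, where outside the rule, Gadd45g, Ccl22 and Lilrb4a were chosen after their values were seen.

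The 25 gene lists were written in advance and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Camera compares a list with all other tested genes. A list whose own fold changes are near or below 0 can therefore be given the direction up. They cover the plasma cell programme, B cell identity, MHC class II, germinal centre and memory genes, STAT6 and STAT3 targets, the interferon response, immunoglobulin constant genes, the unfolded protein response, secretion, cell cycle, MYC, BCL2 family, B cell receptor signalling, NF-kB, homing, cytokine receptors, metabolism, and markers of fibroblasts, T and NK cells and myeloid cells. Calls were repeated with an estimated correlation, and are said in the text to differ where they did. Alternatives tried were median of ratios scaling, immunoglobulin genes removed before scaling, no filter, only the groups compared, a replicate block, and each library left out in turn. Chosen after seeing the data were no scaling, pseudocounts of 0.5 and 5 TPM, a mean of at least 20 TPM, the ribosomal RNA percent as a covariate, and leaving out the 2 libraries with the fewest estimated reads.

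The fit was tested on simulated data with 200 changed genes. For IL-21 against none in IgE cells (9168 genes) it recovered 11.7% of 2-fold, 63.9% of 4-fold and 91.7% of 8-fold changes, with 8 false calls among 109. For the mean of IgE against IgG1 (9165 genes) it recovered 82.8%, 98.2% and 96.6%, with 5 false of 165, and for IL-13 against none in IgG1 cells (9202 genes) 4.7%, 71% and 90.5%, with 2 false of 106. Each setting was simulated without repeats, with the same overdispersion (0.077) for all genes and no other difference between groups. Real genes can differ in spread, so these shares are not the accuracy of the real calls. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.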

Results

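The libraries came from mouse splenic B cells grown on fibroblasts that expressed CD40L and BAFF, signals that a B cell otherwise receives from helper T cells and stroma. The donors were C57BL/6 mice of 8 weeks that carried an IgE reporter, and their cells received no added cytokine, IL-4, IL-13, IL-21, or IL-21 with IL-13. The labels are ambiguous about a pre-culture with IL-4. Cells without added cytokine may thus have met IL-4 before, and a comparison with them need not show a first exposure. CD19-positive, propidium iodide-negative cells were sorted by the IgE reporter (15 libraries) or by surface IgG1 (14 libraries). The kind of sort marker thus changed with the isotype, so a difference between isotypes cannot be told apart from one between gates. Each of the 10 groups held 3 libraries, except IgG1 cells without added cytokine, which held 2. The comparisons asked how IgE cells differed from IgG1 cells and how each cytokine changed either isotype. The unit was TPM, a length-scaled share of the library's transcripts, from 3' end libraries, listed for 25939 genes, of which 10804 were at 0 in every library and 10626 were tested. Gapdh was listed at 0 in 22 libraries and Tuba1b in all 29, so a listed 0 was not read as absence of the transcript.

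Immunoglobulin genes held a larger share of TPM in IgE than in IgG1 cells: 11.2 ± 0.849% without added cytokine (mean ± SD, n = 3), against 1.53 ± 0.0630% in IgG1 cells (n = 2). With IL-4 that share was 4.65 ± 0.0423% in IgE cells and 1.89 ± 0.121% in IgG1 cells, and with IL-21 it was 10.7 ± 2.45% and 3.26 ± 0.660% (n = 3 each). The ribosomal RNA genes Rn18s and Rn45s held between 3.86% and 31.2% of TPM per library. Their share was 27.2 ± 5.70% in IgE and 16.9 ± 11.4% in IgG1 cells with IL-13, and 23.1 ± 8.26% and 15.1 ± 8.27% with IL-21 (n = 3 each). TPM keeps no sequencing depth. The spacing of the lowest values gave an estimate of 646821 to 1625560 assigned reads per library, with a median of 1040732. Between 75.9% and 84.1% of the low values lay within 0.2 of a whole number of such steps. Detected genes numbered 7647 to 10514 per library, with a mean of 8090 in IgE cells and 9361 in IgG1 cells given IL-21. Pearson correlations between libraries across genes ranged from 0.706 to 0.881, and genes are not independent replicates.

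Ighe, the constant gene of IgE (chromosome 12, 113269260 to 113273248, minus strand, GRCm38), stood at 12826 ± 1330 TPM in IgE cells without added cytokine and at 292 ± 90.9 TPM in IgG1 cells (mean ± SD, n = 3 and n = 2). In IgG1 cells it was 1880 ± 352 TPM with IL-4 and at most 556 ± 36.0 TPM in the other cultures (n = 3 each). Ighg1, the constant gene of IgG1 (chromosome 12, 113325240 to 113330523, minus strand), was highest with IL-21, at 11483 ± 1557 TPM in IgE cells and 7091 ± 1780 TPM in IgG1 cells. Without added cytokine Ighg1 was 906 ± 426 TPM in IgE cells and 1456 ± 141 TPM in IgG1 cells. Jchain, which joins secreted IgM and IgA into polymers, was 10615 ± 431 TPM in IgE cells and 303 ± 37.3 TPM in IgG1 cells without added cytokine. With IL-4 it was 2095 ± 329 TPM and 359 ± 38.2 TPM.

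**Figure D1:**
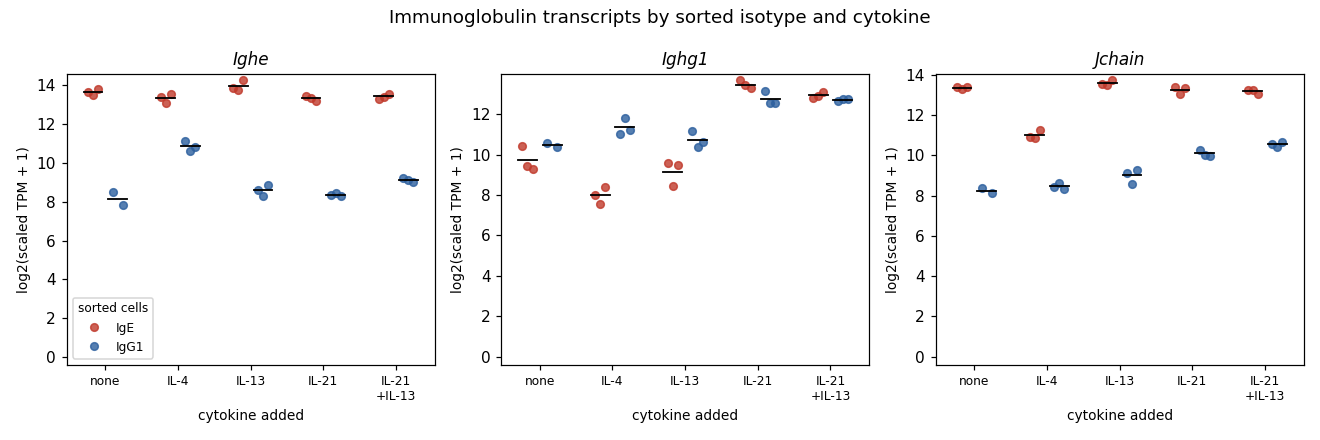
Level of Ighe, Ighg1 and Jchain in log2(scaled TPM + 1) on the vertical axis against the added cytokine on the horizontal axis, with 1 point per library (red IgE cells, blue IgG1 cells) and a black line at the mean of each group. Ighe and Jchain of IgE cells lay above those of IgG1 cells in all 5 cultures, Ighg1 was highest with IL-21 in either isotype, and Jchain of IgE cells was lowest with IL-4 (mean 2095 TPM).

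The plasma cell programme, as a list of genes, was higher in IgE cells in every culture. As a mean over the 5 cultures Ighe was higher by log2 4.53 (SE 0.08, adjusted p = 1.5e-24) and Jchain by 3.61 (SE 0.07, adjusted p = 1.1e-23). Derl3, which removes misfolded proteins from the endoplasmic reticulum (ER), was 232 TPM against 17.2 TPM (log2 fold change 3.92, SE 0.37, adjusted p = 1.1e-08). Txndc5, an ER protein disulfide isomerase, was 531 TPM against 68.4 TPM (2.99, SE 0.13, adjusted p = 9.9e-16). The plasma cell regulators Xbp1 (1.78, SE 0.08), Prdm1 (1.85, SE 0.25) and Irf4 (1.05, SE 0.12) were higher in IgE cells, with adjusted p of 4.0e-15, 5.5e-06 and 2.5e-07. Igha, the IgA constant gene, was higher too (3.67, SE 0.35, adjusted p = 1.3e-08). So were Ly6c2 (3.32), Fkbp11 (3.32), Pon3 (3.20), Eaf2 (3.08), Hid1 (3.05) and the syndecan gene Sdc1 (1.27, SE 0.32, adjusted p = 0.0088). In the IL-4 culture Xbp1 (0.57, adjusted p = 0.34), Irf4 (0.60, adjusted p = 0.95) and Prdm1 (1.225) did not pass. With IL-13 Prdm1 (1.89, adjusted p = 0.0605) and Irf4 (0.79, adjusted p = 0.11) did not pass, nor did Prdm1 without added cytokine (1.295, adjusted p = 0.78). Sdc1 passed in no single culture, from -0.063 with IL-21 to 3.16 without added cytokine (adjusted p = 0.052). Lower in IgE cells in the mean were the early response gene Fosb (-2.96, SE 0.28, adjusted p = 1.1e-08), the survival gene Bcl2a1b (-2.22, SE 0.40, adjusted p = 0.00034), Plac8 (-2.52), Egr4 (-2.37), Kynu (-2.30) and Ighg1 (-0.96, SE 0.13, adjusted p = 9.2e-06). The B cell genes Fcer2a (the low affinity IgE receptor CD23; -1.86, SE 0.21), Aicda (the class switch enzyme AID; -1.27, SE 0.19), Il4ra (-1.05, SE 0.13) and Il21r (-0.59, SE 0.12) were lower as well, with adjusted p of 2.6e-07, 3.5e-05, 1.2e-06 and 0.0017.

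By limma, 524 genes were higher and 666 lower in IgE cells at an adjusted p under 0.05, and 587 of the 1190 differed at least 2-fold. The median log2 fold change over all tested genes was -0.15, and without scaling between libraries the split was 340 higher and 2011 lower. Bach2, a repressor of plasma cell genes, was lower (-0.90, adjusted p = 0.043), but this call was lost in 19 of 29 fits that left out 1 library. The proliferation gene Mki67 was higher (0.53, adjusted p = 0.024), and lost its call without IgG1 no added cytokine replicate 2, without IgG1 IL-21 replicate 3 or without IgG1 IL-13 replicate 1. Ighm (0.52, adjusted p = 0.20), Il13ra1 (0.74, adjusted p = 0.21), Socs1 (-0.34, adjusted p = 0.80) and Pax5 (0.05, adjusted p = 0.97) did not pass the test.

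Secretion genes moved together in that mean. Of 27 plasma cell programme genes 23 were higher and none lower (median log2 fold change 1.73, camera adjusted p = 9.9e-59), the same 23 when adjusted over the list alone. Protein secretion had 21 of 26 genes higher (25 adjusted over the list alone, median 1.16, adjusted p = 1.8e-39), among them Sec61b (1.29, SE 0.09) and Lman1 (1.42, SE 0.10). The unfolded protein response had 17 of 23 higher (17 higher and 1 lower adjusted over the list alone, adjusted p = 2.7e-34), led by the chaperone Hsp90b1 (2.07, SE 0.06). Immunoglobulin constant genes had 7 of 12 higher and 2 lower, unchanged when adjusted over the list alone (median 1.38, adjusted p = 8.1e-17). B cell identity had 10 of 24 lower and 1 higher (12 and 1 adjusted over the list alone, median -0.74, adjusted p = 7.5e-05), with Spib (-1.70, SE 0.14) and Cd22 (-1.04, SE 0.10) among them. Memory and resting B cell genes had 8 of 17 lower (10 adjusted over the list alone, median -1.22, adjusted p = 8.2e-06), including the trafficking regulator Klf2 (-2.21, SE 0.32). MHC class II presentation (median -0.51, adjusted p = 0.0026), NF-kB targets (-0.65, 0.0019) and MYC and ribosome biogenesis (-0.45, 0.0085) were lower by camera. Oxidative phosphorylation was higher only relative to the other genes (median 0.06, camera adjusted p = 0.0022). The median over all tested genes was -0.15. B cell receptor signalling was lower (-0.43, adjusted p = 0.014; adjusted p = 0.065 with an estimated correlation).

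The remaining lists did not pass the camera test in that mean. These were the interferon response (adjusted p = 0.10), S phase genes (0.19), STAT3 targets (0.21), germinal centre programme (0.50), homing and adhesion receptors (0.50), glycolysis and hypoxia (0.50), cytokine receptors (0.57), STAT6 targets (0.62), the BCL2 family (0.86), cholesterol synthesis (0.86) and G2/M genes (0.95). Their medians lay between -0.47 (S phase genes) and 0.13 (interferon response). For STAT3 targets, the germinal centre programme, STAT6 targets, the BCL2 family, cholesterol synthesis and G2/M genes the median and mean were negative while camera gave the direction as up. Markers of other cell types did not pass either: fibroblast feeder markers (12 genes, median 0.12, adjusted p = 0.36), T and NK cell markers (6 genes, -0.86, adjusted p = 0.13) and myeloid, mast cell and basophil markers (2 genes, adjusted p = 0.95, median 0.15 with camera direction down). Cd3e, a T cell gene, was listed at 0 in all 29 libraries.

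Within single cultures between 41 genes (IL-4) and 602 (IL-21) differed between the isotypes, and with only the libraries compared between 1 (no added cytokine) and 289 (IL-21 and IL-13). Without added cytokine IgE cells had more Ighe (log2 fold change 5.49, SE 0.19), Jchain (5.13, SE 0.17), the light chain gene Igkc (3.68, SE 0.19), Txndc5 (3.45, SE 0.31) and Xbp1 (2.39, SE 0.20), with 3.45e-08 (Txndc5) as the highest adjusted p. They had less Fosb (-4.41, SE 0.68, adjusted p = 0.00029). With IL-4 the gaps were 2.48 for Ighe (SE 0.17, adjusted p = 2.0e-10), 2.54 for Jchain (SE 0.15, adjusted p = 2.9e-11) and 2.45 for Txndc5 (SE 0.28, adjusted p = 3.0e-06). Ighg1 (-3.38, SE 0.29, adjusted p = 2.4e-08) and the early response gene Egr1 (-2.36, SE 0.16, adjusted p = 1.7e-10) were lower. Ly6c2 with IL-4 averaged 52.3 TPM in IgE cells and was listed at 0 in every IgG1 library. With IL-21 IgE cells had more Igha (6.07, SE 0.76, adjusted p = 4.8e-06), the mucosal homing receptor Ccr10 (4.80, SE 0.82, adjusted p = 0.00036) and Prdm1 (2.79, SE 0.55, adjusted p = 0.0016). They had less Cd40 (-4.01, SE 0.70, adjusted p = 0.00047) and Fcer2a (-3.95, SE 0.46, adjusted p = 1.2e-06). Aicda was 6.48 TPM in IgG1 cells and was listed at 0 in all 3 IgE libraries (adjusted p = 4.8e-05). With IL-13 the ER gene Fkbp11 (5.41, SE 0.66, adjusted p = 3.5e-06) and Gadd45g (2.25, SE 0.31, adjusted p = 3.1e-05) were higher and Fosb (-5.21, SE 0.61, adjusted p = 2.0e-06) lower. With IL-21 and IL-13 Igha (5.58, SE 0.76, adjusted p = 1.8e-05) was higher, and the inhibitory receptor gene Lilrb4a (8.47 against 226 TPM) and Klf2 (-4.62, SE 0.69, adjusted p = 6.8e-05) were lower.

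Limma called 85 genes higher and 11 lower in IgE cells without added cytokine, 31 and 10 with IL-4, 263 and 339 with IL-21, 159 and 125 with IL-13, and 214 and 257 with IL-21 and IL-13. Without scaling between libraries the split was 14 and 10 with IL-4, 158 and 964 with IL-21, 120 and 406 with IL-13, and 133 and 436 with IL-21 and IL-13. With the ribosomal RNA percent as a covariate it was 135 and 66 with IL-13. Leaving out 1 library took the total from 96 to 44 without added cytokine (IgG1 replicate 2) and from 41 to 22 with IL-4 (IgG1 replicate 3). It took the total from 602 to 379 with IL-21 (IgG1 replicate 3) and from 471 to 297 with IL-21 and IL-13 (IgG1 replicate 2). With 3 libraries on each side chance alone separates 10% of genes without overlap. Among all tested genes 12.1% were so separated with IL-4, 14.8% with IL-13, 18.7% with IL-21 and 19.6% with IL-21 and IL-13. The plasma cell programme was higher in IgE cells in each culture, with 16 of 27 genes called without added cytokine, 8 with IL-4, 19 with IL-21, 15 with IL-13 and 19 with IL-21 and IL-13, and no gene lower. Adjusted over the list alone these were 20, 16, 22, 21 and 22, with 1.91e-37 (IL-4) as the highest camera adjusted p. Ighg1 did not pass the test between the isotypes with IL-21 (0.72, adjusted p = 0.17) or with IL-21 and IL-13 (0.22, adjusted p = 0.80).

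Preset genes called within the single cultures follow. Ighe was higher in IgE cells by 4.99 (SE 0.17) with IL-21, 5.37 (SE 0.17) with IL-13 and 4.31 (SE 0.17) with both. Jchain was higher by 3.16, 4.59 and 2.62 (SE 0.15 each) and Xbp1 by 2.22, 1.82 and 1.93 (SE 0.18 each). Irf4 was higher with IL-21 (1.32, SE 0.26, adjusted p = 0.0016) and without added cytokine (1.53, adjusted p = 0.0030; 0.142 without IgG1 replicate 2). With both cytokines the calls for Irf4 (1.03, adjusted p = 0.018) and Prdm1 (2.06, adjusted p = 0.025) were lost when any 1 of 3 and any 1 of 6 libraries was left out, at most 0.135 (IgG1 replicate 1) and 0.0938 (IgE replicate 2). Ighg1 was lower in IgE cells with IL-13 (-1.56, SE 0.29, adjusted p = 0.0016). Il4ra was lower with IL-21 (-1.68, SE 0.28, adjusted p = 0.00029) and with both (-1.32, SE 0.28, adjusted p = 0.0052), as was Fcer2a with both (-2.87, SE 0.46, adjusted p = 0.00015). Some calls depended on single libraries. Bach2 was lower with IL-21 (-2.31, adjusted p = 0.028), lost without any 1 of 4 libraries (at most 0.13, IgG1 replicate 3). With IL-13 Aicda (-1.63, adjusted p = 0.032), Il21r (-1.08, adjusted p = 0.028) and Il4ra (-1.21, adjusted p = 0.014) were lower, lost without any 1 of 5, 5 and 3 libraries (at most 0.111 without IgE replicate 1, 0.0962 without IgG1 replicate 1 and 0.0821 without IgG1 replicate 2).

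**Figure D2:**
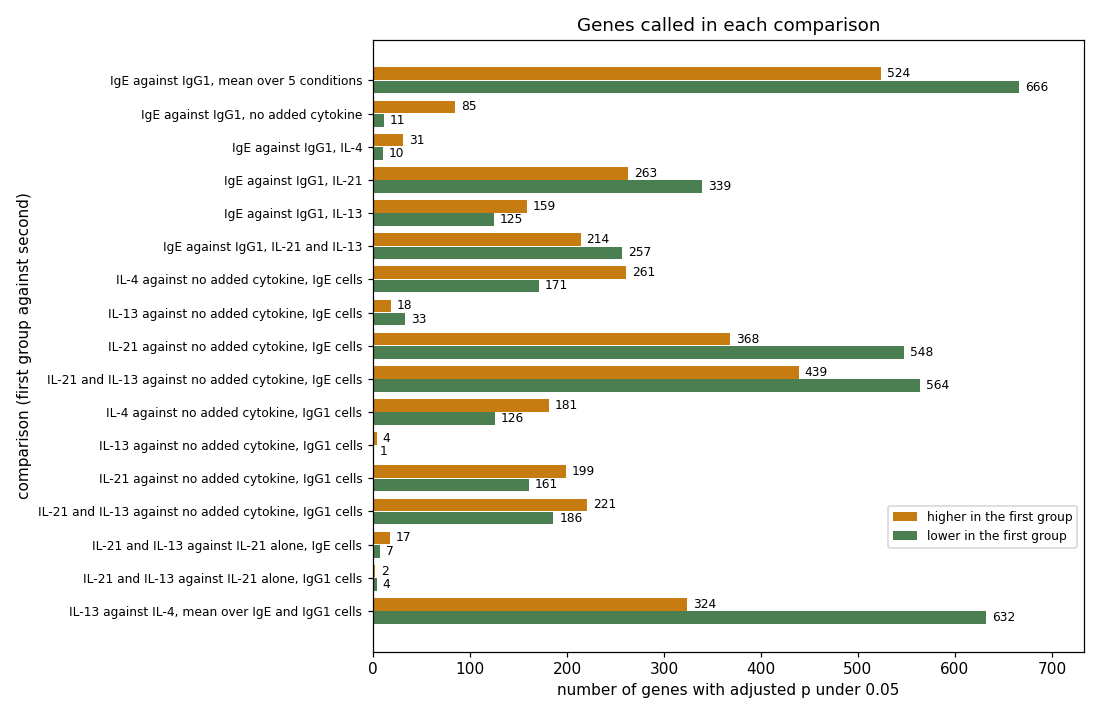
Number of genes with an adjusted p under 0.05 on the horizontal axis for each comparison on the vertical axis, with 1 bar for genes higher in the group named first and 1 bar for genes lower. IgE cells given IL-21 with IL-13 had 439 genes higher and 564 lower than without cytokine, and IgG1 cells given IL-13 had 4 higher and 1 lower.

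IL-4 raised cell cycle genes in IgE cells and lowered most of their antibody transcripts. Thy1, a surface glycoprotein better known from T cells and fibroblasts, rose from 2.49 ± 2.24 to 281 ± 45.2 TPM in IgE cells (log2 fold change 6.51, SE 0.70, adjusted p = 7.5e-07, n = 3 each). The matrix protein gene Mfap5 rose from 1.33 ± 2.30 to 160 ± 31.3 TPM (6.54, SE 1.21, adjusted p = 0.0012). Also higher were the stress gene Gadd45g (3.94, SE 0.31, adjusted p = 3.7e-09), Aicda (2.98, SE 0.42, adjusted p = 5.1e-05), the chemokine gene Ccl22 (2.72, SE 0.50, adjusted p = 0.0012), Il4ra (2.11, SE 0.28, adjusted p = 2.5e-05) and Mki67 (2.19, SE 0.34, adjusted p = 0.00014). The chemokine receptor gene Ccr6 fell from 117 ± 29.7 to 2.67 ± 3.23 TPM (-5.41, SE 0.57, adjusted p = 6.2e-07), and the signalling adaptor gene Bank1 fell too (-3.67, SE 0.58, adjusted p = 0.00020). Jchain (-2.35, SE 0.15, adjusted p = 1.7e-10), Igkc (-1.72, SE 0.17, adjusted p = 2.2e-07), Ighm (-2.67, SE 0.54, adjusted p = 0.0032), Ighg1 (-1.74, SE 0.29, adjusted p = 0.00040) and Irf4 (-1.27, SE 0.26, adjusted p = 0.0032) were lower. Bach2 was listed at 0 in all 3 libraries given IL-4 (adjusted p = 0.013; 0.0699 without IgE no added cytokine replicate 1). Sdc1 was lower (-2.57, adjusted p = 0.036), lost without any 1 of 5 libraries (at most 0.162, IgE IL-4 replicate 3). Ighe (-0.30, adjusted p = 0.46), Xbp1 (-0.27, adjusted p = 0.54), Prdm1 (-0.96, adjusted p = 0.45) and Fcer2a (0.96, adjusted p = 0.32) did not pass the test.

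In IgE cells limma called 261 genes higher and 171 lower with IL-4, and 277 in total without IgE IL-4 replicate 3. Without scaling between libraries 70.7% of 399 calls were higher, against 60.4% in the main fit. Of 25 G2/M genes 18 were higher (23 adjusted over the list alone, median 2.80, camera adjusted p = 5.4e-33), led by the ubiquitin enzyme gene Ube2c (4.20, SE 0.42). Of 25 S phase genes 11 were higher (15 adjusted over the list alone, median 1.96, adjusted p = 5.7e-21), with the DNA ligase gene Lig1 (2.78, SE 0.22) among them. Cholesterol synthesis had 5 of 19 genes higher (11 adjusted over the list alone, adjusted p = 8.6e-09), including Fdps (3.32, SE 0.70). Glycolysis and hypoxia had 6 of 22 (8 adjusted over the list alone, median 0.75, adjusted p = 8.6e-08), including Ldha (1.61, SE 0.22). Immunoglobulin constant genes had 7 of 12 lower, also when adjusted over the list alone (median -1.25, adjusted p = 1.4e-11). The plasma cell programme had 8 of 27 lower (9 adjusted over the list alone, median -0.90, adjusted p = 1.6e-06). STAT6 targets, the genes downstream of the IL-4 receptor, did not pass as a list in IgE cells (3 of 15 higher and 1 lower, unchanged when adjusted over the list alone, median 0.31, adjusted p = 0.14).

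IgG1 cells shared much of this response, and lists of secretion genes that did not pass in IgE cells were higher. Thy1 rose from 1.56 ± 2.21 to 339 ± 50.3 TPM (7.38, SE 0.78, adjusted p = 7.2e-07, n = 2 and n = 3), and Gadd45g (3.33, SE 0.35, adjusted p = 7.2e-07), Aicda (3.01, SE 0.47, adjusted p = 0.00021), Mki67 (2.39, SE 0.38, adjusted p = 0.00023) and Il4ra (1.88, SE 0.31, adjusted p = 0.00045) were higher. The replication helicase gene Mcm5 gained 5.23 (SE 0.52, adjusted p = 2.0e-07). Ighe rose from 292 ± 90.9 to 1880 ± 352 TPM (adjusted p = 1.5e-09), a gain of 15.1% of its level in IgE cells given IL-4. Xbp1 (1.55, SE 0.20, adjusted p = 1.4e-05), Pim1 (1.82, SE 0.18, adjusted p = 2.0e-07) and Hsp90b1 (1.19, SE 0.16, adjusted p = 2.0e-05) were higher. Ighg1 (0.87, adjusted p = 0.20) and Jchain (0.24, adjusted p = 0.69) did not pass. Ighm was lower (-2.58, adjusted p = 0.014), lost without any 1 of 3 libraries (at most 0.208, IgG1 no added cytokine replicate 2). Lower were Ccr6 (-6.55, SE 0.64, adjusted p = 2.0e-07), the membrane protein gene Ms4a4c (-6.04, SE 0.77, adjusted p = 1.5e-05), Bank1 (-5.54, SE 0.65, adjusted p = 4.5e-06) and the B cell receptor kinase gene Syk (-2.39, SE 0.33, adjusted p = 4.8e-05). STAT6 targets were higher as a list (6 of 15, 8 higher and 1 lower adjusted over the list alone, median 1.55, camera adjusted p = 3.8e-09), and so was the unfolded protein response (7 of 23, 11 higher and 4 lower adjusted over the list alone, adjusted p = 2.0e-06). Protein secretion was higher as well (2 of 26, 4 adjusted over the list alone, median 0.50, adjusted p = 4.9e-06). In IgE cells these last 2 lists had adjusted p of 0.58 and 0.47. IgE cells in the IgG1 sort with IL-4 were not excluded (pattern B below). Such cells could account for part of the rises of Ighe, Xbp1, Hsp90b1 and these lists. With IL-4 Hsp90b1 averaged 1977 TPM in IgE cells and 768 TPM in IgG1 cells. B cell receptor signalling was lower (6 of 26, 9 lower and 1 higher adjusted over the list alone, median -0.81, adjusted p = 9.3e-10). Limma called 181 genes higher and 126 lower, but only 125 in total without IgG1 no added cytokine replicate 2. Without scaling between libraries 73.7% of 327 calls were higher, against 59% in the main fit. Of the genes higher with IL-4, 116 were called in both isotypes where 4.45 would coincide if calls were independent, and of those lower 64 against 2.03. Both comparisons use the same estimate of each gene's spread, so calls are not independent and such expected numbers can be too low.

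IL-21 raised cell cycle and secretion genes in IgE cells and lowered antigen presentation. Ube2c rose from 16.6 to 549 TPM (5.09, SE 0.42, adjusted p = 3.6e-09), Mki67 gained 2.90 (SE 0.34, adjusted p = 1.6e-06) and the cytokine receptor gene Il2rb 4.21 (SE 0.69, adjusted p = 0.00018). Ighg1 was higher by 3.75 (SE 0.29, adjusted p = 1.2e-09) and the IgM assembly chaperone gene Mzb1 by 1.25 (SE 0.11, adjusted p = 2.2e-08). Ighe (-0.31, adjusted p = 0.31), Jchain (-0.11, adjusted p = 0.73) and Prdm1 (0.64, adjusted p = 0.54) did not pass. Aire, the regulator of self antigens in the thymus, fell from 161 ± 10.8 to 0.215 ± 0.372 TPM (-7.10, SE 0.52, adjusted p = 5.2e-10, n = 3 each), and the T cell costimulator gene Icosl from 62.1 to 0.751 TPM (-5.35, SE 0.68, adjusted p = 6.2e-06). The MHC class II genes H2-Oa (-6.00, SE 0.66, adjusted p = 5.6e-07) and H2-Aa (-2.02, SE 0.14, adjusted p = 3.4e-10), Fcer2a (-5.17, SE 0.46, adjusted p = 1.4e-08), Il4ra (-1.95, SE 0.28, adjusted p = 3.3e-05) and Il21r (-1.51, SE 0.27, adjusted p = 0.00062) were lower. Aicda was listed at 0 in all 3 IgE libraries given IL-21 and was lower (adjusted p = 4.5e-08). Sdc1 (-2.41, adjusted p = 0.032) and Bach2 (-2.30, adjusted p = 0.021) were lower, lost without any 1 of 5 and any 1 of 4 libraries (at most 0.135 without IgE IL-21 replicate 2, and 0.0967 without IgE no added cytokine replicate 1). Pax5 was listed at 0 with IL-21 (adjusted p = 0.038), and this call was lost whichever of the 6 libraries was left out (at most 0.166, IgE no added cytokine replicate 3).

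In IgE cells limma called 368 genes higher and 548 lower with IL-21, and 600 in total without IgE no added cytokine replicate 2. The median log2 fold change was -0.26 over all tested genes and -0.04 over genes with a mean of at least 20 TPM. G2/M genes (19 of 25 higher, 21 adjusted over the list alone, median 2.90, camera adjusted p = 2.7e-30), S phase genes (11 of 25, 14 adjusted over the list alone, adjusted p = 1.2e-17), protein secretion (12 of 26, 17 adjusted over the list alone, adjusted p = 3.3e-17) and the unfolded protein response (12 of 23, 13 adjusted over the list alone, median 1.13, adjusted p = 4.1e-14) were higher. Oxidative phosphorylation was higher by a median of 0.70 (adjusted p = 1.3e-10), while mitochondrial genes held 4.82 ± 0.841% of TPM with IL-21 and 9.13 ± 1.01% without (n = 3 each). MHC class II presentation had 11 of 15 genes lower (12 adjusted over the list alone, median -1.69, adjusted p = 3.4e-17). B cell identity had 10 of 24 lower and 2 higher (14 and 3 adjusted over the list alone, median -1.23, adjusted p = 4.5e-05), with Cd22 (-2.06, SE 0.22) and Cd19 (-1.19, SE 0.17) among the lower genes. STAT3 targets, the genes downstream of the IL-21 receptor, did not pass as a list (2 of 18 higher and 2 lower, 4 and 3 adjusted over the list alone, adjusted p = 0.20, median 0.10 and mean -0.03 with camera direction up).

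In IgG1 cells IL-21 raised Ighg1 by 2.26 (SE 0.33, adjusted p = 6.8e-05), Jchain by 1.86 (SE 0.17, adjusted p = 6.7e-08) and Mki67 by 2.91 (SE 0.38, adjusted p = 1.7e-05). Mcm5 (5.93, SE 0.52, adjusted p = 3.6e-08) and the Src family kinase gene Hck (0.252 to 53.3 TPM, 5.46, SE 0.70, adjusted p = 1.6e-05) were higher too. Aire (-6.74, SE 0.58, adjusted p = 3.6e-08), Icosl (-5.17, SE 0.77, adjusted p = 9.3e-05) and H2-Aa (-1.64, SE 0.16, adjusted p = 1.4e-07) fell in these cells as well. Ighe (0.19, adjusted p = 0.78), Xbp1 (0.40, adjusted p = 0.37) and Prdm1 (-0.86, adjusted p = 0.61) did not pass. Aicda (-1.95, adjusted p = 0.017), Fcer2a (-2.28, adjusted p = 0.0078) and Il21r (-1.20, adjusted p = 0.022) were lower in the fit of all libraries. Their calls were lost without IgG1 no added cytokine replicate 1 (0.21, 0.0821 and 0.0644) or replicate 2 (0.0717, 0.0962 and 0.325), and in 1 or 2 further fits. MHC class II presentation had 7 of 15 genes lower (8 adjusted over the list alone, camera adjusted p = 6.5e-12), and G2/M genes had 18 of 25 higher (23 adjusted over the list alone, median 2.89, adjusted p = 3.6e-33). The plasma cell programme was higher (median 0.40, adjusted p = 0.032; adjusted p = 0.13 with an estimated correlation). Limma called 199 genes higher and 161 lower, 268 and 101 without scaling between libraries, and 147 in total without IgG1 no added cytokine replicate 2. Of the genes higher with IL-21, 126 were called in both isotypes where 6.89 would coincide if calls were independent, and of those lower 106 against 8.3.

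IL-21 with IL-13 gave the most called genes in IgE cells, 1003 against 916 with IL-21 alone. With 1 library left out the ranges overlapped (675 to 873 and 600 to 862), so a wider response than to IL-21 alone was not shown. The nucleotide reductase gene Rrm2 (5.02, SE 0.71, adjusted p = 2.2e-05), the cyclin gene Ccna2 (4.63, SE 0.63, adjusted p = 1.2e-05), Gadd45g (4.35, SE 0.31, adjusted p = 3.4e-10), Ighg1 (3.22, SE 0.29, adjusted p = 1.6e-08) and Mki67 (2.78, SE 0.34, adjusted p = 2.4e-06) were higher. The interferon-induced genes Ifi27 (122 to 0.454 TPM, -6.49, SE 0.60, adjusted p = 2.6e-08) and Isg15 (-5.33, SE 1.24, adjusted p = 0.0054), Aire (-7.06, SE 0.52, adjusted p = 5.2e-10), Lilrb4a (436 to 8.47 TPM, -6.26, SE 0.56, adjusted p = 1.3e-08), Klf2 (-3.93, SE 0.69, adjusted p = 0.00033) and Fcer2a (-3.48, SE 0.46, adjusted p = 7.1e-06) were lower. So were Il4ra (-1.87, SE 0.28, adjusted p = 4.7e-05) and Il21r (-1.57, SE 0.27, adjusted p = 0.00028). Ighm (-1.75, adjusted p = 0.040), Xbp1 (0.64, adjusted p = 0.019), Aicda (-1.39, adjusted p = 0.036) and Pax5 (listed at 0, adjusted p = 0.036) lost their calls in 3, 3, 4 and 5 of 6 fits that left out 1 library. The highest adjusted p were 0.311 and 0.188 without IgE IL-21 and IL-13 replicates 1 (Ighm) and 3 (Aicda), and 0.0975 and 0.164 without IgE no added cytokine replicates 2 (Xbp1) and 3 (Pax5). In IgG1 cells Jchain (2.32, SE 0.17, adjusted p = 7.6e-10), Ighg1 (2.22, SE 0.33, adjusted p = 6.8e-05), Mki67 (3.38, SE 0.38, adjusted p = 1.4e-06) and Gadd45g (2.36, SE 0.35, adjusted p = 8.0e-05) were higher and Aire was lower (-5.82, SE 0.58, adjusted p = 2.7e-07). Ighe (0.96, adjusted p = 0.0023) and Xbp1 (adjusted p = 0.00077) were higher and Il21r (-1.30, adjusted p = 0.011) and Il4ra (-1.19, adjusted p = 0.028) lower. Without IgG1 no added cytokine replicate 2 Ighe (0.234), Il21r (0.243) and Il4ra (0.343, also lost in 3 other fits) lost their calls, and without replicate 1 Xbp1 did (0.0745). Limma called 439 genes higher and 564 lower in IgE cells and 221 and 186 in IgG1 cells, where leaving out IgG1 no added cytokine replicate 2 left 158. Of the genes higher, 167 were called in both isotypes where 9.13 would coincide if calls were independent, and of those lower 126 against 9.87. In IgE cells the memory and resting B cell genes were lower (median -1.27, camera adjusted p = 0.0013), as were NF-kB targets (-1.16, 0.0026) and cytokine receptors (-1.16, 0.0059). In IgG1 cells the plasma cell programme was higher (7 of 27 higher and 1 lower, 11 and 2 adjusted over the list alone, median 0.83, adjusted p = 2.8e-07).

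With IL-13 alone few genes were called. By limma, 1179 of 10626 genes in IgE cells and 507 in IgG1 cells had an unadjusted p under 0.05. Few calls need not mean a small effect. In simulated data for IL-13 in IgG1 cells 4.7% of 2-fold changes were recovered. In IgE cells Gadd45g rose from 43.8 ± 24.1 to 642 ± 85.8 TPM (3.97, SE 0.31, adjusted p = 1.9e-08, n = 3 each) and the replication clamp factor gene Pclaf from 31.4 to 99.9 TPM (1.62, SE 0.22, adjusted p = 0.00038). The mitochondrial iron-sulfur factor gene Lyrm4 (-4.48, SE 0.54, adjusted p = 5.2e-05) and the peroxisomal thiolase gene Acaa1a (-3.37, SE 0.50, adjusted p = 0.0012) fell. Il21r was lower (-1.35, adjusted p = 0.023), lost without any 1 of 3 libraries (at most 0.125, IgE no added cytokine replicate 2). Ighe (0.33, adjusted p = 0.50), Aicda (-0.31, adjusted p = 0.87) and Mki67 (1.06, adjusted p = 0.19) did not pass. In IgG1 cells 5 genes were called with all libraries in the fit. Of these, Thy1 (4.14, adjusted p = 0.039), Cdca3 (2.87, adjusted p = 0.039), Mcm5 (2.83, adjusted p = 0.035) and Klhdc2 (113 to 355 TPM, 1.65, adjusted p = 0.028) were higher and Cib3 fell from 7.35 TPM to a listed 0 (adjusted p = 0.0037). None of the 5 held its call in every fit that left out 1 library. With only the libraries compared 14 genes were called, all lower and 0 of them among the 5. Without IgG1 no added cytokine replicate 2 limma called no gene (277 had an unadjusted p under 0.05), and Cib3 fell below the level needed for testing without either library of that group. Limma called 18 genes higher and 33 lower in IgE cells, 24 and 24 with median of ratios scaling, and 6 and 21 without scaling. The total was 18 without IgE no added cytokine replicate 2 and also with the ribosomal RNA percent as a covariate. With only the libraries compared limma called none (870 had an unadjusted p under 0.05). G2/M genes were higher as a list in IgE cells (2 of 25, 6 adjusted over the list alone, median 1.06, camera adjusted p = 2.0e-11), as was the unfolded protein response (1 of 23, 6 adjusted over the list alone, median 0.43, adjusted p = 7.6e-06). In IgG1 cells S phase genes were higher (1 of 25, 3 adjusted over the list alone, median 0.40, adjusted p = 0.00024). So were STAT6 targets (0 of 15, 2 adjusted over the list alone, median 0.22, adjusted p = 0.0044; adjusted p = 0.090 with an estimated correlation).

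When IL-13 was added to IL-21 few genes were called. By limma, 994 of 10626 genes in IgE cells and 475 in IgG1 cells had an unadjusted p under 0.05. In IgE cells the DNA polymerase subunit gene Pole2 rose from 0.422 to 36.2 TPM (4.60, SE 0.57, adjusted p = 0.00011) and Gadd45g from 217 to 835 TPM (1.99, SE 0.31, adjusted p = 0.0030). Aicda was 8.08 TPM with IL-13 and was listed at 0 in all 3 libraries without it (adjusted p = 0.00036). The lymphotoxin gene Lta was 20.8 TPM against a listed 0 (adjusted p = 0.018). Haao, an enzyme of tryptophan breakdown, averaged 25.0 TPM with IL-21 and was listed at 0 in the 3 libraries given both cytokines (adjusted p = 4.6e-05). In IgG1 cells 2 genes were called higher, Fam174c and Egr1 (0.97, SE 0.16, adjusted p = 0.011), and 4 lower, C8g, B3gnt8, Ccl6 and Chn2. None of these held its call in every fit that left out 1 library. Chn2 (6.10 TPM against a listed 0, adjusted p = 0.0074) fell below the level needed for testing without IgG1 IL-21 replicate 2 or 3. The plasma cell programme was higher in IgG1 cells given both cytokines (0 of 27 genes called, 6 higher and 1 lower adjusted over the list alone, median 0.46, camera adjusted p = 1.1e-07). No list passed in IgE cells (lowest adjusted p 0.25). Limma called 17 genes higher and 7 lower in IgE cells, and 87 in total without IgE IL-21 replicate 1. A pseudocount of 5 TPM left 9, and with only the libraries compared limma called none (504 had an unadjusted p under 0.05). Another split of the same 6 libraries called 23. In IgG1 cells only 2 genes were called without IgG1 IL-21 replicate 2.

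Directly against IL-4, IL-13 left more Ccr6 (5.58, SE 0.40, adjusted p = 7.4e-10), Ms4a4c (4.89, SE 0.49, adjusted p = 1.6e-07), Ighm (2.91, SE 0.38, adjusted p = 8.9e-06), Bach2 (2.62, SE 0.45, adjusted p = 0.00025) and Jchain (1.55, SE 0.11, adjusted p = 4.3e-10), as a mean over both isotypes. It gave less of the transcription factor genes Msc (-4.64, SE 0.49, adjusted p = 3.2e-07) and Batf (-3.84, SE 0.85, adjusted p = 0.0035), of Thy1 (-3.78, SE 0.49, adjusted p = 8.1e-06), Aicda (-2.66, SE 0.30, adjusted p = 9.9e-07) and Il4ra (-2.26, SE 0.20, adjusted p = 1.7e-08). Irf4 was higher (0.78, SE 0.18, adjusted p = 0.0056) and Mki67 lower (-1.31, SE 0.24, adjusted p = 0.00053). Ighe was lower in that mean (-0.82, SE 0.12, adjusted p = 4.0e-05), and Xbp1 (0.02, adjusted p = 0.97), Ighg1 (0.26, adjusted p = 0.52) and Prdm1 (0.80, adjusted p = 0.23) did not pass. For 3 of these genes the isotypes lay on opposite sides. With IL-13 and IL-4 Ighe averaged 16191 and 10492 TPM in IgE cells against 391.5 and 1880 TPM in IgG1 cells, Xbp1 942 and 601 against 269 and 405 TPM, and Ighg1 607 and 261 against 1735 and 2726 TPM. Limma called 324 genes higher and 632 lower with IL-13 than with IL-4. G2/M genes (18 of 25 lower, 22 adjusted over the list alone, median -1.66, camera adjusted p = 1.3e-17), glycolysis and hypoxia (10 of 22 lower and 1 higher, 12 and 1 adjusted over the list alone, median -1.06, adjusted p = 2.6e-07) and STAT6 targets (7 of 15 lower and 1 higher, 7 and 2 adjusted over the list alone, median -0.83, adjusted p = 0.0031) were lower with IL-13. B cell receptor signalling was higher (9 of 26, 12 higher and 1 lower adjusted over the list alone, median 0.56, adjusted p = 2.6e-07).

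**Figure D3:**
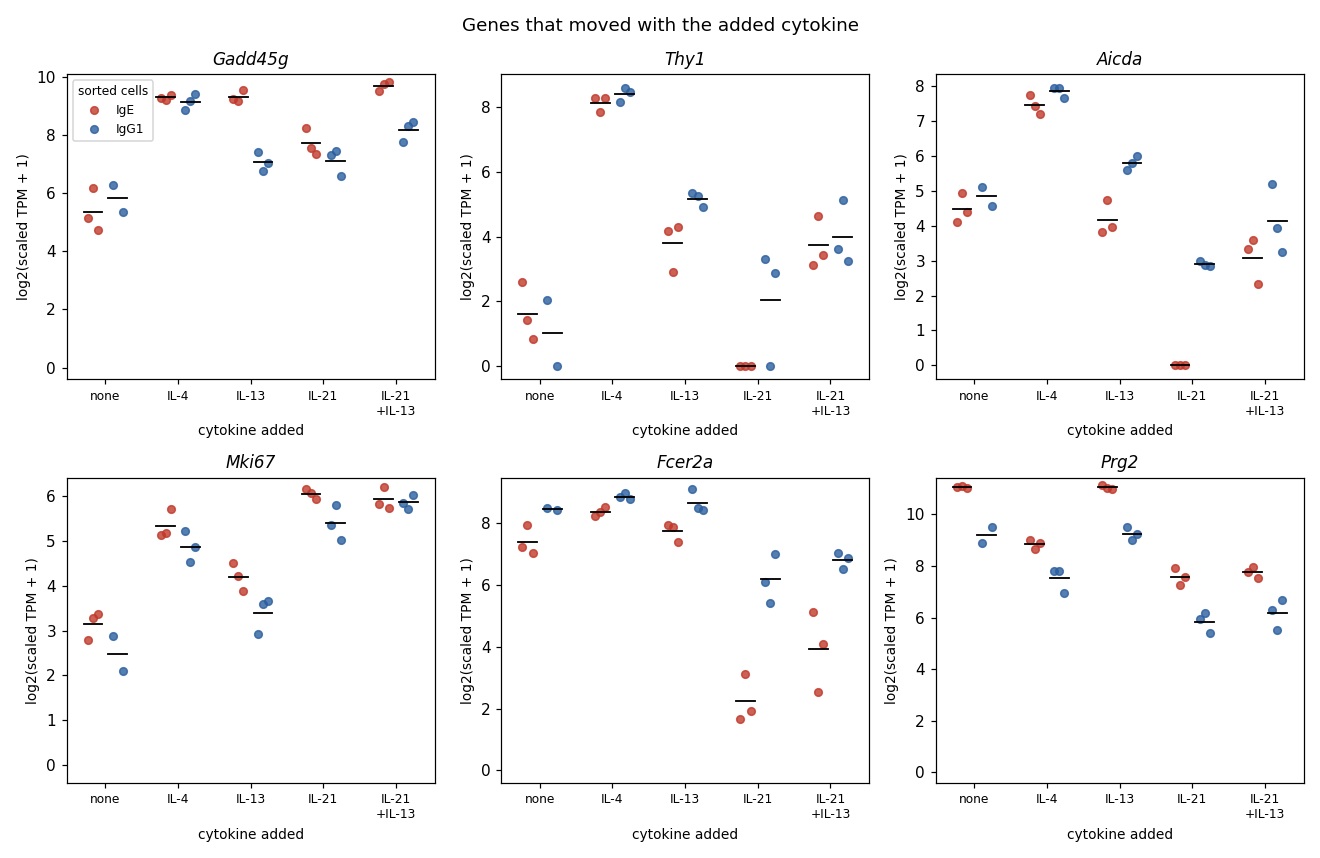
Level of 6 genes in log2(scaled TPM + 1) on the vertical axis against the added cytokine on the horizontal axis, with 1 point per library (red IgE cells, blue IgG1 cells) and a black line at the mean of each group. Thy1 and Aicda were highest with IL-4 (means of 281 and 177 TPM in IgE cells), Gadd45g was above the culture without cytokine in all 4 cytokine cultures, and Prg2 and Fcer2a of IgE cells were lowest with IL-21 (193.7 and 4.20 TPM).

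A test of the difference between the isotypes' responses called 10 genes for IL-4, 10 for IL-21 and 15 for IL-21 with IL-13. For IL-13 limma called none, and 555 genes had an unadjusted p under 0.05. Xbp1 rose with IL-4 in IgG1 cells and not in IgE cells (difference -1.82, SE 0.26, adjusted p = 0.00074), and Ighe differed by -3.00 (SE 0.26, adjusted p = 8.4e-08). IgE cells in the IgG1 sort with IL-4 were not excluded as a source of part of these differences (pattern B below). Jchain rose in IgG1 cells alone with IL-21 (-1.97, SE 0.23, adjusted p = 2.4e-05) and with IL-21 and IL-13 (-2.50, SE 0.23, adjusted p = 3.6e-07). Mzb1 rose in IgE cells alone (1.54, SE 0.17, adjusted p = 2.0e-05, and 1.09, SE 0.17, adjusted p = 0.0024). Leaving out IgG1 no added cytokine replicate 2 left 6 genes for IL-4, 2 for IL-21 and 5 for IL-21 with IL-13. Bcl6 and Il21 were listed at 0 in all 29 libraries, and Socs3 did not reach the level needed for testing. The transgene product Cd40lg was at most 12.4 TPM, and Tnfsf13b, which encodes BAFF, at most 7.9 TPM, in any library.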

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

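The tests of pattern A (Ighg1 with IL-21) and pattern C (Thy1 and Mfap5 with IL-4) were chosen after the results were seen. What singles out the genes and lists below is a difference between the isotypes' responses to the same cytokine, tested as an interaction.

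The response to IL-4 differed between IgE and IgG1 cells for 10 genes. The differences (IgE minus IgG1) were -3.00 for Ighe (adjusted p = 8.4e-08), -2.59 for Jchain (8.4e-08), -1.95 for Igkc (0.00017), -1.82 for Xbp1 (0.00074) and -1.50 for Pim1 (0.0028), and these 5 calls held whichever library was left out. Jchain fell in IgE cells (-2.35) and Igkc likewise (-1.72), while Xbp1 and Pim1 rose in IgG1 cells (1.55 and 1.82). For Ighe, Xbp1 and the secretion lists, part of the difference could come from IgE cells in the IgG1 sort (pattern B). Pcsk4 (-4.89) lost its call without IgG1 no added cytokine replicate 1 (adjusted p = 0.0515), and Ighg1 (-2.61) and Egr1 (-1.47) without replicate 2 (0.0704 and 0.0662). Sdf2l1 (-1.97) lost it when any 1 of 10 libraries was left out, with the highest adjusted p (0.41) without IgG1 no added cytokine replicate 2. The value for Cib3 (3.00) rests on the IgG1 libraries without cytokine, since the gene was listed at 0 in the other groups. Its call was lost when any 1 of 9 libraries was left out (at most 0.112, without IgG1 IL-4 replicate 3), and for each cytokine it was not tested without either of those IgG1 libraries. The medians over lists were -1.03 for immunoglobulin constant genes (adjusted p = 7.4e-16), -0.79 for the plasma cell programme (3.8e-11), -0.74 for the unfolded protein response (3.2e-11), -0.45 for protein secretion (6.8e-05) and -0.21 for STAT6 targets (6.4e-05). The call for STAT6 targets was lost when immunoglobulin genes were removed (-0.16, adjusted p = 0.298).

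With IL-21 the isotypes' responses differed for 10 genes, and Mzb1 (1.54) and Jchain (-1.97) held whichever library was left out. Hck (-5.70), Pou2af1 (1.19) and Sh3bgrl3 (-1.14) lost their calls without IgG1 no added cytokine replicate 2 (adjusted p = 0.127 each). Pole2 (-4.47), B3gnt8 (-4.38), Cd22 (-1.79) and Cotl1 (-1.51) lost theirs without replicate 1 of that group (0.228, 0.142, 0.152 and 0.228). The calls for Pou2af1, Sh3bgrl3, Pole2, B3gnt8, Cd22 and Cotl1 were lost without either library of that group, and those for Pole2, Cotl1, B3gnt8 and Sh3bgrl3 were lost without 7, 6, 3 and 3 libraries in all, each left out alone. Cib3 (3.00) lost its call when any 1 of 8 libraries was left out (at most 0.103, without IgG1 IL-21 replicate 3).

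With IL-21 and IL-13 the count was 15, and Mzb1 (1.09), Haao (-5.42), Jchain (-2.50) and Ly6d (-1.58) held whichever library was left out. Mndal (-1.94), Bcl11a (-2.94), Ncf1 (-2.08), Cfp (-2.64) and Gimap3 (-3.57) lost their calls without IgG1 no added cytokine replicate 2 (adjusted p = 0.0583, 0.165, 0.257, 0.295 and 0.322). Nfkbia (1.12), Lilrb4a (-4.55) and Cotl1 (-1.79) lost theirs without replicate 1 of that group (0.0981, 0.0993 and 0.0694). Each left out alone, 10 libraries ended the call for Gimap3, 8 for Cfp, 6 for Ncf1, 5 for Bcl11a, and 3 each for Nfkbia and Lilrb4a. Cib3 (3.00) lost its call when any 1 of 7 libraries was left out (at most 0.0789, without IgG1 IL-21 and IL-13 replicate 2). Memory and resting B cell genes had a median of -1.81 (adjusted p = 4.4e-05).

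Pattern A is that with IL-21 Ighg1 was not lower in IgE cells (11483 ± 1557 TPM) than in IgG1 cells (7091 ± 1780 TPM). If the IgE sort with IL-21 were nearly all IgG1 cells, 63 genes higher in IgE cells would lie near the IgG1 level. These were called at least 2-fold higher both without added cytokine and with IL-13. Their lower quartile with IL-21 was 1.75 (median 2.07, 59 higher), which argues against a sort made up so. A smaller share of IgG1 cells, or IgG1 cells rich in these genes, cannot be excluded by this test. Ighe reads counted to Ighg1 would keep the ratio of the genes fixed, but the lowest ratio with IL-21 was 9.77 times the highest without cytokine (1.07 to 1.18 against 0.0437 to 0.109), which argues against this as well. A hypothesis that IL-21 raises Ighg1 transcripts in switched cells of either isotype needs a rise in IgG1-sorted cells, which was 2.26. The same rise would be seen if some IgG1 cells lay in the IgE sort, so it does not decide between the 2. The hypothesis was found and tested on the same data.

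Pattern B is that Ighe was higher with IL-4 in IgG1-sorted cells, at 1880 ± 352 against 292 ± 90.9 TPM. To give that gain, IgE cells would have to make up 15.1% of the IgG1 sort. Of 29 genes higher in IgE cells, 1 lay below that share of its IgE level in every IgG1 library with IL-4. This was Ly6c2, listed at 0. In their highest IgG1 library Txndc5, Fkbp11 and Jchain reached 18.1%, 18.5% and 19.2%, while by group means Fkbp11 (12.9%) lay below the share as well. The share rests on the gain of Ighe, while these genes were judged by their full level, which includes the IgG1 cells' own transcripts. From no cytokine to IL-4, Jchain went from 303 to 359 TPM and Txndc5 from 45.8 to 42.2 TPM in IgG1 cells. In IgE cells both fell, from 10615 to 2095 and from 482 to 238 TPM. A like fall in IgG1 cells could hide a gain, so gains do not decide either. With Ly6c2 of uncertain level and Fkbp11 on either side of the share between libraries, a sort that held IgE cells cannot be told apart from Ighe transcripts in IgG1 cells. No biological explanation was tested.

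Pattern C is that Thy1 and Mfap5, known from fibroblasts, were higher with IL-4. Feeder fibroblasts carried into the sort with IL-4 would raise other fibroblast genes alike, but 11 such genes had a median of -0.58 (-2.14 to 0.49), which argues against this. No biological explanation was tested.

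Other splits of the same libraries into groups gave fewer genes than the real ones. For the mean of IgE against IgG1 (1190 genes) 1 of 100 splits was as large, the real one, and 318 was the highest other. For IL-13 against IL-4 (956 genes) these were 1 of 100 and 170. In both the share was under 0.05, so a random split of these libraries seldom gave so many genes. Other splits leave the real difference in the spread, which lowers their counts. A difference in mouse, culture or sort shared by a group's libraries would not be seen. For 3 libraries against 3, the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, was as large in each comparison. The real value and the highest other were 41 and 2 for IgE against IgG1 with IL-4, 602 and 3 with IL-21, 284 and 3 with IL-13, and 471 and 1 with IL-21 and IL-13. Against no added cytokine in IgE cells they were 432 and 1 for IL-4, 51 and 5 for IL-13, 916 and 6 for IL-21, and 1003 and 2 for IL-21 and IL-13. For IL-21 and IL-13 against IL-21 alone they were 24 and 23 in IgE cells and 6 and 3 in IgG1 cells.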

How the results depend on the processing

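Settings chosen after seeing the data were no scaling, pseudocounts of 0.5 and 5 TPM, a mean of at least 20 TPM, the ribosomal RNA percent as a covariate, and leaving out the 2 libraries with the fewest estimated reads. The planned count-model alternative was not run, because the values are TPM. Of 1241 calls for named genes, 788 held whichever library was left out and 637 under every other alternative that tested the gene. Of 173 list results, 141 and 122 did. The cause was not tested for any change below unless given. Without scaling, Cd44 turned from 0.29 (adjusted p = 0.016) to -0.01 (0.947) in the mean of IgE against IgG1, and its call was lost without IgG1 no added cytokine replicate 2 (0.0673). In simulated data for IL-21 in IgE cells 63.9% of 4-fold changes were recovered over all genes and 91.7% among genes of at least 50 TPM. For 2-fold changes these were 11.7% and 7.7%, and the mean of IgE against IgG1 recovered 82.8% of 2-fold changes.

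Counts that moved by over 1.5 times follow. Median of ratios scaling gave 1 gene for the difference of the isotypes' responses to IL-13. Immunoglobulin genes removed before scaling gave 27 for IgE against IgG1 with IL-4, and 5 and 1 for the differences with IL-4 and IL-13. With no filter (15135 genes) IL-13 in IgG1 cells had 13, and the differences 16 (IL-4), 3 (IL-13) and 17 (IL-21). With only libraries of the groups compared, which leaves fewer samples to estimate the spread, IgE against IgG1 had 1 (none), 12 (IL-4), 215 (IL-21), 64 (IL-13) and 289 (IL-21 and IL-13). In that setting the cytokines gave 271, 0, 347 and 493 in IgE cells (IL-4, IL-13, IL-21, both), and 173, 14 and 166 in IgG1 cells (IL-4, IL-13, IL-21), where the 14 were lower and shared 0 with the 5 called with all libraries. IL-21 and IL-13 against IL-21 alone gave 0 in IgE and 2 in IgG1 cells, and the differences 4 (IL-13), 17 (IL-21) and 25 (both). No scaling gave 2351 for the mean of IgE against IgG1 (340 higher, 2011 lower), 24, 1122 and 526 with IL-4, IL-21 and IL-13, and 27 for IL-13 in IgE cells. A pseudocount of 5 TPM gave 3 for IL-13 in IgG1 cells, 9 for IL-21 and IL-13 against IL-21 in IgE cells, and 1 for the difference with IL-13. A mean of at least 20 TPM (3444 genes) gave 3 for IL-21 and IL-13 against IL-21 in IgG1 cells, and 1 and 31 for the differences with IL-13 and both. The ribosomal RNA percent as a covariate gave 18 for IL-13 in IgE cells. Without the 2 libraries of fewest estimated reads, IL-13 in IgG1 cells had 2, IL-21 and IL-13 against IL-21 in IgE cells 40, and the differences 3, 23 and 24 (IL-13, IL-21, both). A pseudocount of 0.5 TPM moved none of the 21 counts by that much. Some totals moved less while their split into higher and lower changed: IgE against IgG1 without cytokine had 86 and 25 with no filter (85 and 11 in the main fit), and with IL-4 40 and 6 at a mean of at least 20 TPM (31 and 10). With the ribosomal RNA percent as a covariate IgE against IgG1 with IL-13 had 135 and 66 (159 and 125). IL-21 and IL-13 against IL-21 in IgE cells had 10 and 12 at a mean of at least 20 TPM and 13 and 3 without scaling (17 and 7).

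No pairing of the libraries by replicate number was seen. Correlations of 14 pairs with the same number were -0.042 to 0.020, and 5 of the 14 correlated best with their own number. With so few libraries per group, noise within libraries could hide a shared mouse or culture, so this check cannot exclude pairing. A replicate block gave 1 gene (Cib3, lower) for IL-13 in IgG1 cells and 3 for IL-21 and IL-13 against IL-21 in IgG1 cells, and within a condition 44 for IgE against IgG1 without cytokine and 24 with IL-4.

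With each library left out in turn, where a group left with 1 library was assumed to vary like the others, IgE against IgG1 ranged from 964 to 1285 for the mean, 44 to 90 without cytokine, 22 to 35 with IL-4, 379 to 588 with IL-21, 200 to 265 with IL-13 and 297 to 411 with both. In IgE cells the ranges were 277 to 332 (IL-4), 18 to 71 (IL-13), 600 to 862 (IL-21) and 675 to 873 (both). In IgG1 cells they were 125 to 224, 0 to 6, 147 to 286 and 158 to 307. IL-21 and IL-13 against IL-21 alone gave 29 to 87 in IgE and 2 to 6 in IgG1 cells, and IL-13 against IL-4 gave 771 to 978. The differences gave 6 to 10 (IL-4), 0 to 3 (IL-13), 2 to 30 (IL-21) and 5 to 25 (both). The lowest counts in IgG1 cells against none, and for the differences other than IL-13, came without IgG1 no added cytokine replicate 2.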

Other observations

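The genes in this part were chosen after their values were seen. Slpi, which encodes a protease inhibitor, rose with IL-21 from 3909 ± 552 to 47002 ± 4255 TPM in IgE cells (3.59, SE 0.16, adjusted p = 2.6e-14) and from 482 ± 4.23 to 7104 ± 1057 TPM in IgG1 cells (3.87, SE 0.18, adjusted p = 6.4e-14). It was higher in IgE than in IgG1 cells in the mean over cultures (2.87, SE 0.07, adjusted p = 9.1e-21). Prg2, which encodes eosinophil major basic protein, fell with IL-21 in IgE cells (-3.49, SE 0.27, adjusted p = 9.6e-10) and in IgG1 cells (-3.36, SE 0.30, adjusted p = 4.4e-08). Klhdc2 rose with IL-4 by 3.06 in IgE cells (SE 0.26, adjusted p = 1.0e-08) and in IgG1 cells (3.06, SE 0.29, adjusted p = 1.3e-07).

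Mfap5 lies next to Aicda on chromosome 6, with 24510 bp between the genes. With IL-4 in IgE cells Mfap5 rose by 6.54 (adjusted p = 0.0012) and Aicda by 2.98 (SE 0.42, adjusted p = 5.1e-05). The inhibitor gene Nfkbia rose in IgE cells given IL-21, from 1618 ± 24.8 to 4650 ± 459 TPM (1.52, SE 0.14, adjusted p = 2.1e-08).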
